A study of Mus musculus with 23 samples.

How the data were processed

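RNA from 23 libraries of mouse ESCs, grown on embryonic fibroblast feeders with serum and LIF per the sample labels, was measured by QuantSeq 3′ tag sequencing of 500 ng total RNA. The deposited values are raw integer counts per gene, made with featureCounts 1.6.0 on the Ensembl 97 annotation of GRCm38, per the file headers; with its default options reads mapping to several places or overlapping several genes are not counted. Per the submitters' processing notes, reads were aligned with STAR 2.5.4b and counted with Subread 2.0.0 on mm10; read trimming is not given in the sources used here. The count files held 55573 genes, of which 55394 had a symbol and 179 had none, the latter taking at most 0.001% of a library's counts; 215 identifiers shared a symbol with another. Mitochondrial genes had 0 counts in all libraries.

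Libraries carrying the same title code (2a, 2b, 2d and 2e, 2 libraries each) were summed and counted as 1 sample, which left 19 samples with 806412 to 10217040 counts. At these depths the floor of 3 counts corresponded to between 0.294 and 3.72 CPM in a sample. Undifferentiated R1 samples of both sets were compared with set as a covariate, and each set was also fitted alone. The difference between sets was tested as an interaction, and lines KO1 and KO2 were compared within each set by group means. KH2 samples were fitted on their own. RA effects, KO against WT after RA and their interaction came from 1 fit of all set 2 samples by group means, in which the KO RA samples were set against the mean of KO1 and KO2.

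Tests were edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3 with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and robust dispersions. All gene p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values of samples and of libraries were scaled by TMM. Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, where at least 5 members were tested. Calls of members were also adjusted over the list alone. The 26 lists covered core and naive pluripotency, LIF-STAT3 response, formative and primed pluripotency, the 2-cell-like state, neuroectoderm, primitive streak with mesoderm and definitive endoderm, primitive and visceral endoderm, trophectoderm, p53 targets, Wnt/β-catenin targets, retinoic acid response and Hox genes, histone chaperones, PP2A, linker and variant histones, mitosis and DNA replication, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, imprinted genes, germline genes, feeder fibroblast markers, Y-linked genes, mitochondrial genes, ribosomal proteins, interferon response and apoptosis regulators. Of the 35 feeder markers, 6 reached 10 CPM in set 1 WT and 16 in set 2 WT, so ESC cultures carry reads of many of them.

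Named genes followed a rule. They were 16 key genes, and the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher group, leaving out predicted and unnamed genes and, for KO against WT, genes without the same sign in each line of each set. Up to 4 members with the smallest adjusted p of each list that passed were added, and for interactions and line comparisons the 3 highest and 3 lowest genes were taken. Some genes that the rule selects are not reported here. Groups, tests, lists, this rule and most alternatives were set before the data were examined. Ratios with 1 to 3 counts on a side carry 95% counting intervals, and a side with 0 counts was given the floor.

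Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, every library as its own sample, the replicate number as a block, sums per line and set, group means per line, all samples in 1 fit, KO1 alone as the RA control, each sample left out in turn, and a camera correlation estimated per list. Each fit was tested on simulated data with 200 changed genes. For KO against WT over both sets it recovered 93% of 2-fold and 96% of 4-fold changes, with 5.50% of its calls false. It recovered 75% of 2-fold changes for Dox, 41% for RA in WT, 54% for KO against WT after RA and 28% for the RA by genotype difference, and called 0 of 20 unchanged lists in each. Simulated genes varied independently and the unchanged lists were drawn at random. The simulation therefore does not test false calls of lists whose genes vary together. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Strandedness, splicing and the edited sequence of Set were not analysed here.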

Results

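The series measured polyadenylated RNA by 3′ tag sequencing (QuantSeq) in mouse embryonic stem cells (ESCs) labelled as SET knockout or as carrying an inducible SETa transgene. SET is a histone chaperone and inhibitor of the phosphatase PP2A. The title and design of the series ask how SET, through p53 and β-catenin, bears on the ESC state and on differentiation. R1 ESCs, a male mouse line, were compared as wild type (WT) and SET knockout (KO) in 2 separately titled sets, each with the KO lines KO1 and KO2. Whether KO1 and KO2 were the same clones in both sets is not given in the sources used here. Set 1 held 2 WT, 2 KO1 and 2 KO2 samples. Set 2 held 2 WT, 2 KO1 and 2 KO2 samples, 1 WT sample after 4 d of retinoic acid (RA, which drives ESCs to differentiate) and 2 KO samples after 4 d of RA, both titled KO1. KH2 ESCs, a line built for doxycycline-controlled transgenes, carried HA-tagged SETa and were sampled with and without 1 μg/mL doxycycline (Dox) for 24 h, with 2 samples each. The 23 libraries made up these 19 samples because libraries sharing a title code were summed; samples are named here by group and title code (1a to 1f, 2a to 2i). Assigned counts per sample ran from 806412 to 1445013 in set 1, from 2833064 to 10217040 in untreated set 2, from 3904924 to 5047363 after RA and from 4848478 to 6472695 in KH2 cells. No label stated that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

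Set itself (ENSMUSG00000054766, GRCm38 chromosome 2, 30057378 to 30072577, plus strand) was lower in all 8 KO samples than in the WT samples of the same set. In set 1 it stood at 961 ± 25.3 CPM (counts scaled to library size; ± SD, n = 2) in WT and 21.0 ± 3.64 (n = 4) in KO, with single KO libraries between 17.6 and 25.4. In set 2 it stood at 1326 ± 181 (n = 2) in WT and 437 ± 132 (n = 4) in KO, with libraries between 508 and 561 in KO1 and between 272 and 429 in KO2. After RA the WT sample held 580 CPM and the 2 KO samples averaged 241 ± 66.6, with libraries at 185 and 277. In KH2 cells Set was at 992 ± 40.3 without and 1197 ± 99.6 with Dox (n = 2 each), a difference that did not pass the test (edgeR adjusted p = 0.175). The edgeR log2 fold change of KO over WT was -3.46 (SE 0.67, adjusted p = 0.00642) over both sets, -5.50 in set 1 and -1.56 in set 2, and the difference between sets of 3.94 passed its own test (adjusted p = 2.48e-06). With counts summed to 1 sample per line and set, the call over both sets was lost (log2 -3.60, adjusted p = 0.184). A 3′ tag lying outside an edited coding exon does not check the coding lesion, so these levels check the labels only as far as the transcript falls.

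**Figure D1:**
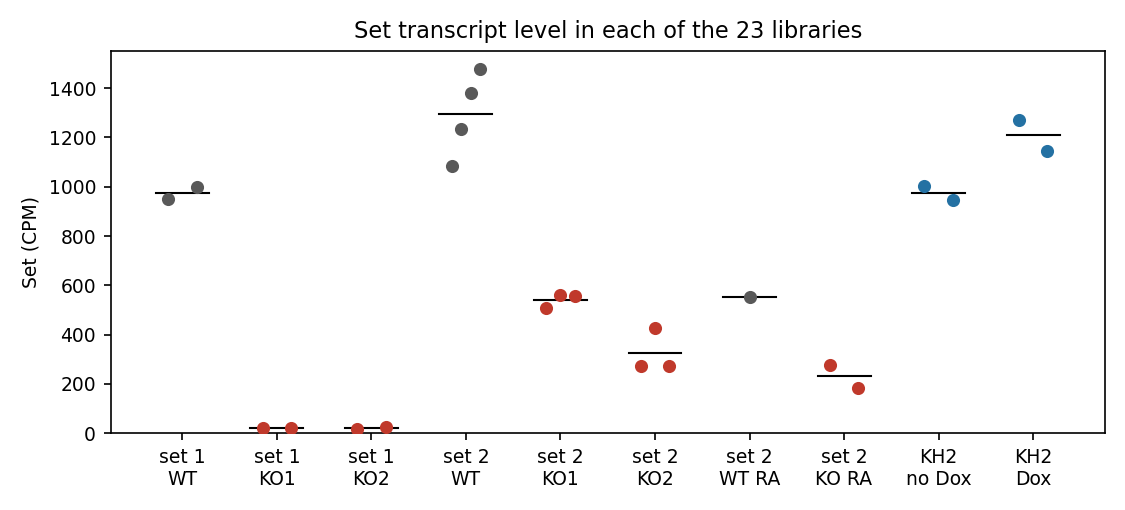
Set transcript level in CPM (y axis) in each of the 23 libraries (points) by group (x axis), with the group mean as a line; grey is WT, red KO and blue KH2. Libraries of set 1 KO sat between 17.6 and 25.4 CPM, those of set 2 KO between 272 and 561, and every untreated KO library lay below the WT libraries of its set.

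Undifferentiated ESCs labelled SET KO, with Set transcript lowered far in set 1 and partly in set 2, had lower naive pluripotency transcripts and higher p53 target and extraembryonic endoderm transcripts. Klf4 (chromosome 4, 55527143 to 55532466), a naive pluripotency factor, fell from 311 ± 48.4 to 105 ± 18.6 CPM in set 1 and from 453 ± 37.4 to 201 ± 36.6 in set 2 (log2 -1.35, SE 0.12, edgeR adjusted p = 6.41e-08). Untreated set 2 libraries were cut into sub-batches A and B at the largest gap along the leading principal component of their profiles. The titles do not name these sub-batches. The gap was 21.2 units, while A spanned 29.8 and B 17.6, so the cut is not sharp. Klf4 differed between the sub-batches. In A it stood at 572 and 514.5 CPM in WT and at 209 to 293 in KO. In B it stood at 284 CPM in both WT libraries and at 157 to 168 in KO. The SD of the summed samples does not show this spread. Cdkn1a (chromosome 17, 29090976 to 29100727), the p53-activated inhibitor of cyclin-dependent kinases, rose from 48.3 ± 15.9 to 208 ± 38.5 CPM in set 1 and from 72.6 ± 1.72 to 198 ± 15.8 in set 2 (log2 1.72, SE 0.15, adjusted p = 5.68e-08). Lefty2, an inhibitor of Nodal signalling, rose by 1.45 (SE 0.11) on the log2 scale (adjusted p = 3.90e-09). Each of these 3 genes moved in its direction in 8 of 8 KO samples. Over both sets, 2194 of 11515 tested genes passed an adjusted p of 0.05, 1200 higher and 994 lower in KO, and 631 of them changed more than 2-fold. With counts summed per line and set 1426 passed.

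Of the 34 core and naive pluripotency genes, 25 fell, 1 rose and 8 were not called (27 and 2 when adjusted over the list alone; camera adjusted p = 6.93e-18, and 0.0112 with an estimated correlation). Esrrb, an activator of the naive network, fell by 1.19 (SE 0.13), the growth factor gene Fgf4 by 0.96 (SE 0.13), Sox2 by 0.79 (SE 0.11) and Klf2 by 0.78 (SE 0.10), all on the log2 scale. Nanog fell by 0.57 (SE 0.13, edgeR adjusted p = 0.00329). In set 2 Nanog was lower in KO in sub-batch A only, at 72.6 to 85.4 CPM against 130 and 160 in WT. In sub-batch B it stood at 107 to 121 CPM in KO and at 105 and 102 in WT. Pou5f1, counted at only 3.34 to 17.1 CPM in the group means, had a log2 change of -0.67 that did not pass (edgeR adjusted p = 0.0831). Reads mapping to several places were not counted, and whether this lowered the level of Pou5f1 was not analysed here. Among 17 tested genes of the LIF-STAT3 response, which sustains ESC self-renewal, 6 fell and 3 rose (8 and 4 when adjusted over the list alone; camera adjusted p = 0.00152, and 0.0155 with an estimated correlation). They included Gbx2 (log2 -2.19), Tfcp2l1 (log2 -0.77) and the STAT feedback inhibitor gene Socs2 (log2 -0.59). The formative and primed pluripotency genes rose as a list, with 10 of 24 higher and 4 lower (12 and 6 when adjusted over the list alone; camera adjusted p = 0.000968, and 0.0155 with an estimated correlation). Lefty1 rose by 1.26 and Wnt8a by 3.10 on the log2 scale, whereas Etv4, a target of FGF signalling, fell by 1.32.

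Of 52 tested p53 targets, 21 rose, 1 fell and 30 were not called, with the same counts when adjusted over the list alone (camera adjusted p = 4.99e-10, and 0.000522 with an estimated correlation). Besides Cdkn1a these were led by the kinase gene Plk2 (log2 1.24, SE 0.15), the peptide transporter gene Tap1 (log2 1.56, SE 0.19) and Mdm2 (log2 0.85, SE 0.11), which encodes the ubiquitin ligase for p53. The transcript of p53 itself, Trp53, stood at 165 CPM in WT and 135 in KO of set 1 and at 117 and 88.5 in set 2 (log2 -0.34, SE 0.14, adjusted p = 0.0931). Of 24 tested apoptosis regulators, 8 rose and 2 fell (8 and 3 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.277). Of 37 genes of mitosis and DNA replication, 8 fell and none rose (9 when adjusted over the list alone; camera adjusted p = 0.000815, and 0.0155 with an estimated correlation). The changes were small, as in Ccnb2 (log2 -0.49) and the DNA polymerase gene Pola1 (log2 -0.42).

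Wnt/β-catenin targets rose as a list with the preset correlation, 11 of 32 higher and 3 lower (13 and 3 when adjusted over the list alone; camera adjusted p = 0.000391). The adjusted p = 0.0666 with an estimated correlation did not pass. Tnfrsf19 (log2 1.27), Id2 (log2 0.91) and Sp5 (log2 2.81) rose, while Lef1, which encodes a transcription factor partner of β-catenin, fell by 0.78 (SE 0.17, adjusted p = 0.00296). Neither Axin2, a feedback target of the pathway (log2 0.47, SE 0.24, adjusted p = 0.175), nor Ctnnb1, which encodes β-catenin (log2 0.29, SE 0.16, adjusted p = 0.226), passed. Primitive streak, mesoderm and definitive endoderm genes had 8 of 19 higher and 1 lower (11 and 1 when adjusted over the list alone; camera adjusted p = 0.000712), with an adjusted p = 0.106 with an estimated correlation. Wnt3 rose by 2.24 and Foxa2 by 0.82 on the log2 scale, and Tcf15, a mesoderm factor gene also expressed in ESCs, fell by 1.77. T (brachyury) had 0 counts in set 1 WT and was at least 10.5-fold higher in set 1 KO, against a floor of 3 counts over the group. Its call over both sets (log2 1.73, adjusted p = 0.0224) was lost without WT sample 2b (adjusted p = 0.0803). In set 2, T was higher in KO in sub-batch B only. In B it stood at 24.3 to 36.8 CPM in KO and at 6.49 and 11.6 in WT, and in A at 3.63 to 6.27 in KO and at 6.28 and 7.55 in WT. Lef1 of set 2 was lower in KO in B only, at 47.05 to 56.0 CPM against 89.8 and 104 in WT. In A, Lef1 stood at 50.8 to 59.2 CPM in KO and at 49.5 and 48.0 in WT. Axin2 was at 16.3 to 21.6 CPM in KO and 6.37 and 7.88 in WT in B. In A, Axin2 was at 7.26 to 10.5 CPM in KO and 7.67 and 14.3 in WT.

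Primitive and visceral endoderm genes rose most broadly, with 18 of 25 higher and 1 lower (21 and 1 when adjusted over the list alone; camera adjusted p = 5.36e-14, and 0.00301 with an estimated correlation). Lamb1, a laminin gene of the basement membrane, rose from 191 ± 21.6 to 517 ± 57.9 CPM in set 1 and from 271 ± 10.4 to 506 ± 51.6 in set 2. Col4a1 rose by 1.43, Pth1r by 1.39 and the endoderm factor gene Sox17 by 1.28 on the log2 scale. Of 13 tested trophectoderm genes, 8 rose and none fell (9 when adjusted over the list alone; camera adjusted p = 2.86e-08, and 0.00301 with an estimated correlation). Among them were the keratin genes Krt19 (log2 2.33, SE 0.22), Krt8 (log2 1.74) and Krt7 (log2 1.92). Markers of embryonic fibroblasts, on which these ESCs were grown, moved the same way. Of 27 such markers 14 rose and none fell (20 when adjusted over the list alone; camera adjusted p = 1.59e-11, and 0.0162 with an estimated correlation), with a median log2 of 1.03. Col1a1, Col1a2 and Col3a1 together rose from 10.6 CPM in set 1 WT to 60.7 in KO1 and 73.9 in KO2, and from 55.6 in set 2 WT to 79.2 and 99.5. The endoderm and fibroblast lists shared 1 member, Sparc, and without it 17 endoderm genes rose.

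**Figure D2:**
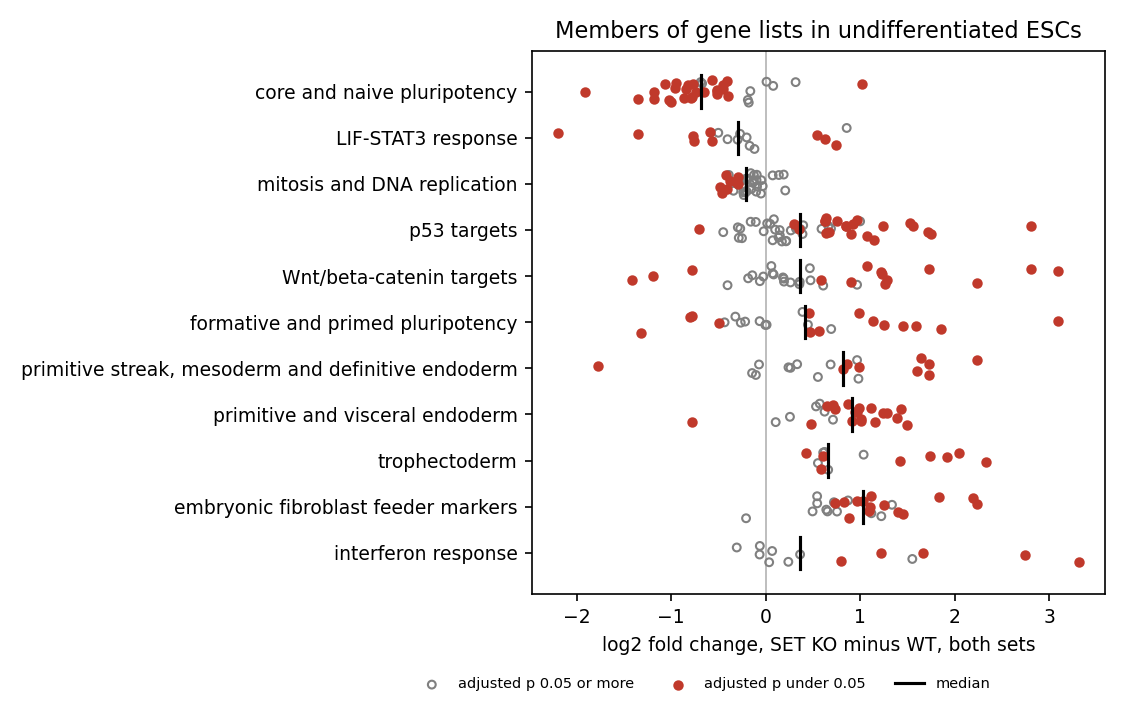
Log2 fold change of SET KO over WT in undifferentiated ESCs over both sets (x axis) for the tested members of 11 gene lists (y axis); each point is a gene, filled where the edgeR adjusted p was under 0.05, and the black bar is the list median. Of 34 pluripotency genes 25 fell, while 18 of 25 endoderm genes and 21 of 52 p53 targets rose.

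The largest rises by the naming rule were in Usp26 (log2 3.55), Trim67 (log2 3.48), the neurofilament gene Nefm (log2 3.08), the neuropeptide precursor gene Vgf (log2 2.94), Sp5, Gbp2 (log2 2.75) and Gbp2b. Besides Set, the largest falls were in Inhbb (log2 -2.67), which encodes an activin and inhibin subunit, Aass (log2 -2.47), the myoblast fusion gene Mymx (log2 -2.42), Igsf21 (log2 -2.22), the noncoding RNA Halr1 (log2 -2.20), Gbx2 and Prmt8 (log2 -2.16). Mymx went from 93.5 ± 8.21 to 11.5 ± 2.51 CPM in set 1 and from 82.7 ± 4.31 to 19.6 ± 3.62 in set 2. Interferon response genes rose, 5 of 13 higher and none lower (6 when adjusted over the list alone; camera adjusted p = 0.000815, and 0.0155 with an estimated correlation), among them Isg15 (log2 3.31), Gbp2, Gbp3 (log2 1.67) and Ifitm3 (log2 0.80). The Isg15 change rested on low counts in set 1, with KO samples at 2.58 to 7.51 CPM. The floor of 3 counts there was 2.08 to 3.72 CPM. Cholesterol synthesis (5 of 25 higher, none lower, 6 when adjusted over the list alone) passed with the preset correlation (camera adjusted p = 0.00625), but had adjusted p = 0.0901 with an estimated correlation. Hmgcs1, which encodes an early enzyme of the pathway, rose by 0.55. Imprinted genes (6 of 24 higher and 2 lower; 9 and 2 when adjusted over the list alone; camera adjusted p = 0.0225) had adjusted p = 0.262 with an estimated correlation, and included H19 (log2 2.13), Peg3 (log2 1.17) and Peg10 (log2 0.88). Of 44 ribosomal protein genes, 1 fell, Rps20 (log2 -0.63), the same with adjustment over the list alone (camera adjusted p = 0.0103), with adjusted p = 0.165 with an estimated correlation.

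The remaining lists did not pass camera in this comparison. Neuroectoderm genes went both ways, 7 of 20 higher and 7 lower, equally when adjusted over the list alone, and the negative list median (log2 -0.19) and the upward direction of the test differed in sign (adjusted p = 0.675). Nes rose (log2 1.15, adjusted p = 0.0190, 0.0520 without WT sample 1a and 0.0805 with counts summed per line and set) and Pax6 fell (log2 -1.25, adjusted p = 0.0275; 0.0537 without WT 1a and 0.0631 without WT 1b). Pax6 rested on few counts, with 5 and 6 in set 1 WT and 0 to 2 in set 1 KO samples. In set 2, Pax6 stood at 1.45 to 3.29 CPM in KO and at 6.95 and 9.27 in WT in sub-batch B. In A, Pax6 stood at 0 to 6.27 CPM in KO and at 4.99 and 6.28 in WT. Retinoic acid response and Hox genes had 4 of 22 higher and 4 lower (5 and 4 when adjusted over the list alone; adjusted p = 0.407). Histone chaperones, the list that holds Set, had 2 of 28 higher and 4 lower (2 and 4 over the list alone; adjusted p = 0.0939). PP2A subunits and inhibitors had 2 of 26 higher and 4 lower (3 and 4 over the list alone; adjusted p = 0.769). Linker and variant histones had 0 of 15 higher and 4 lower, equally over the list alone (adjusted p = 0.0808). Germline genes silenced by promoter methylation had 3 of 20 higher and 5 lower, also equally (adjusted p = 0.529). Glycolysis and hypoxia genes had 4 of 31 higher and 5 lower (4 and 6 over the list alone; adjusted p = 0.403). Unfolded protein and amino acid stress genes had 4 of 26 higher and 2 lower, equally over the list alone (adjusted p = 0.789). The 2-cell-like list had 2 and the Y-linked list 3 tested members, too few for a test, and the mitochondrial genes had no counts.

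Set by set, 1200 of 9764 tested genes passed in set 1 (702 higher, 498 lower in KO) and 1165 of 12681 in set 2 (715 higher, 450 lower). Krt19 rose in both sets (log2 2.76 in set 1 and 2.11 in set 2), as did Mdm2 (log2 0.89 and 0.84) and Lefty2 (log2 1.45 and 1.47), while Mymx fell in both (log2 -3.02 and -2.03). Across the 9666 genes tested in both, the KO effects correlated with r = 0.685 and rho = 0.575; genes are not independent replicates. Of these genes 573 were called in both sets, 363 higher in both (43.5 if the lists were independent), 210 lower in both (20.7) and 0 in opposite directions (29.2 and 30.9). The count in set 1 was 570 without WT sample 1a and 776 without KO2 sample 1e. In set 2 it was 195 without WT sample 2b, 502 without 2a, 748 without KO1 sample 2d, 607 without KO2 sample 2e and 2335 without KO2 sample 2f. It was 759 with every library as its own sample, and 1604 when sub-batch was added to that fit as a covariate. The sub-batches were cut from the profiles of these same libraries after group means were removed. Adding them therefore lowers the remaining spread and tends to raise the count by construction. The set 2 sub-batches lay along their leading principal component (28.1% of the variance), each holding WT, KO1 and KO2 libraries. The KO count was 434 within sub-batch A and 1583 within sub-batch B, with every library as its own sample. The pooled count was 759 in that way and 1165 with summed samples.

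**Figure D3:**
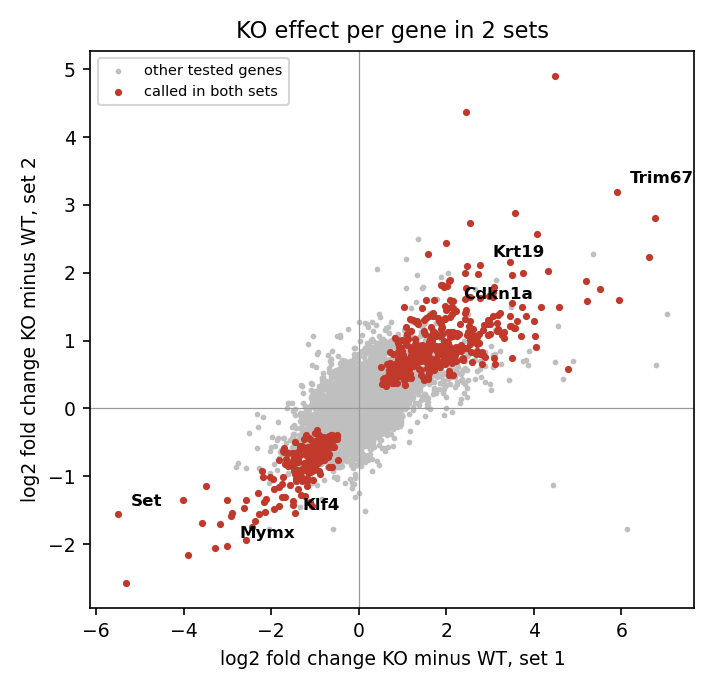
Log2 fold change of SET KO over WT per gene in set 1 (x axis) and set 2 (y axis) for the 9666 genes tested in both; red points are the 573 genes called in both sets and grey points the rest. All red points lie in the quadrants of equal sign, 363 higher and 210 lower in KO.

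The KO effect differed between the sets for 99 of 11950 genes, 19 with a higher and 80 with a lower value in set 2. Stra8, a retinoic acid induced germline gene, fell in KO by 3.49 on the log2 scale in set 1 and by 1.15 in set 2 (difference 2.35, SE 0.38, edgeR adjusted p = 0.00146). Sema3c, a secreted axon guidance factor gene, differed by -4.41 (adjusted p = 0.00889), Ccn4 by -4.39 (adjusted p = 0.00889) and the skeletal actin gene Acta1 by -4.47 (adjusted p = 0.0369). These 3 had 1 or 2 counts in set 1 WT, and their KO to WT ratios there were 31.4 (95% interval 5.44 to 1257), 36.9 (6.44 to 1476) and 68.7 (18.9 to 570). Triml1 differed by 1.43 (adjusted p = 0.0333). Fibroblast markers had a lower KO effect in set 2 (5 of 27 lower, 7 when adjusted over the list alone; camera adjusted p = 1.70e-14, and 0.0374 with an estimated correlation; median log2 -1.29). Trophectoderm (3 of 14 lower, 3 over the list alone; adjusted p = 0.000276, and adjusted p = 0.121 with an estimated correlation) went the same way. So did imprinted genes (3 of 24 lower, 5 over the list alone; adjusted p = 0.000359, and adjusted p = 0.160 with an estimated correlation). Glycolysis genes went the opposite way (1 of 31 higher; 5 higher and 1 lower over the list alone; adjusted p = 0.0418, and adjusted p = 0.370 with an estimated correlation). Without single samples the count was 22 (WT 1a), 44 (WT 1b), 52 (KO2 1e), 43 (WT 2a), 41 (WT 2b), 52 (KO1 2d) and 62 (KO2 2e). It was 171 without a low-count filter, 78 with every library as its own sample and 184 when sub-batch, cut from these same libraries, was added to that fit. Of the 6 genes named for this difference, Set and Stra8 kept their calls in every fit, while Acta1 (adjusted p = 0.171), Sema3c (adjusted p = 0.171), Ccn4 (adjusted p = 0.0787) and Triml1 (adjusted p = 0.127) lost theirs without WT sample 1a. Acta1 (adjusted p = 0.248), Ccn4 (adjusted p = 0.123) and Triml1 (adjusted p = 0.113) also lost theirs without WT 1b, and Sema3c without WT 2b (adjusted p = 0.0695). Acta1 and Triml1 did so without KO1 1c (adjusted p = 0.0632 and 0.0614), KO2 1e (0.0720 and 0.0558), WT 2a (0.112 and 0.206), WT 2b (0.105 and 0.0935), KO1 2d (0.0563 and 0.0816) and KO2 2e (0.0504 for both), and Triml1 without KO2 1f (0.0574). Ccn4 also lost its call by DESeq2 (adjusted p = 0.110).

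The lines KO1 and KO2 differed in few genes. In set 1 only Ddx3y, a Y-linked helicase gene, passed (4.62 ± 3.51 CPM in KO1 and 64.3 ± 2.62 in KO2, n = 2 each, log2 3.59, edgeR adjusted p = 0.000344). There were 710 genes at an unadjusted p under 0.05 and 1 gene by DESeq2. In set 2 the Y-linked genes Ddx3y (30.9 ± 0.727 and 6.77 ± 0.717 CPM, log2 -2.21, adjusted p = 7.89e-05), Uty (log2 -1.91) and Eif2s3y (log2 -1.80) were lower in KO2. There were 698 genes at an unadjusted p under 0.05 and 2 by DESeq2. Ddx3y was thus higher in KO2 in set 1 and lower in KO2 in set 2. WT differed too, as Ddx3y, Uty and Eif2s3y stood at 0.413, 0 and 1.22 CPM in set 1 WT and at 65.7, 21.6 and 23.6 in set 2 WT. Why Y-linked transcripts were almost absent from set 1 WT was not tested. In set 1 the count was 2 without WT sample 1a, 3 without WT 1b, 4 without KO2 1e, 196 without KO1 sample 1c and 25 without a low-count filter. In set 2 it was 1 without KO1 sample 2c, 1 without KO2 2f, 1 with every library as its own sample, 22 without a low-count filter (13 higher, 9 lower) and 56 without KO2 sample 2e (31 higher, 25 lower). Uty and Eif2s3y lost their calls without KO1 sample 2c (adjusted p = 0.243 for both), KO1 2d (0.501 and 0.374) and KO2 2f (0.361 and 0.113), and Eif2s3y without KO2 2e (0.0647). Both also lost them with every library as its own sample (adjusted p = 0.254 and 0.275), and Uty by DESeq2 (adjusted p = 0.0525). Against WT, 1123 genes passed for KO1 and 965 for KO2 in set 1, and 1153 for KO1 and 596 for KO2 in set 2. Endoderm genes were higher in KO2 of set 1 as a list (0 of 25 called, 2 over the list alone; camera adjusted p = 0.00264), with adjusted p = 0.618 with an estimated correlation. Pluripotency genes (0 of 34 called, 0 over the list alone) and fibroblast markers (0 of 30 called, 0 over the list alone) were higher in KO2 of set 2 (camera adjusted p = 0.00601 for both), each with adjusted p = 0.831 with an estimated correlation. KO1 sample 2c was a sub-batch B library and KO2 sample 2f a sub-batch A library. These list differences in set 2 may therefore follow sub-batch instead of line.

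Dox in KH2 cells carrying the SETa transgene changed few genes by more than 2-fold. Set itself did not pass (adjusted p = 0.175). Dox without the transgene was not analysed here, so effects of the drug are not separated from those of SETa. Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), a β-globin gene, had 0 counts of 9758753 without Dox and 738 of 11759929 with Dox, at least 204-fold higher against a floor of 3 counts over the group. Ccn2, a matricellular growth factor gene, rose from 654 ± 149 to 1383 ± 172 CPM (log2 1.09, SE 0.12, edgeR adjusted p = 1.88e-05). The imprinted RNA H19 fell from 112 ± 17.6 to 51.9 ± 3.12 (log2 -1.10, SE 0.14, adjusted p = 5.85e-05). The endogenous 3′ tag measures an induced transgene only where its transcript ends in the annotated gene. In all, 229 of 12723 tested genes passed, 114 higher and 115 lower, and 37 changed more than 2-fold. By the naming rule the other high genes were Bahcc1 (log2 1.53), the noncoding RNA Xist (log2 1.39), Plaur (log2 1.29), Bloc1s3 (log2 1.18), Sall3 (log2 1.10) and Snhg6 (log2 1.09). The other low genes were Cdc42ep2 (log2 -1.17), the granin gene Scg2 (log2 -1.16), Serf1 (log2 -1.13), Vaultrc5 (log2 -1.06), Ubtd1 (log2 -0.99), Lipt1 (log2 -0.99) and Pde1b (log2 -0.98).

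Pluripotency genes were higher with Dox as a list, 3 of 34 up and 1 down (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0224), but had adjusted p = 0.749 with an estimated correlation. Dppa5a (log2 0.78), Tfcp2l1 (log2 0.71) and Zfp42 (log2 0.50) were up and Dppa4 (log2 -0.43) down. The p53 targets had 4 of 51 up and 1 down (11 and 3 over the list alone; adjusted p = 0.0385, and adjusted p = 0.749 with an estimated correlation). Mdm2 rose by 0.51 (SE 0.11), Epha2 by 0.72 and Eda2r by 0.55, and Ddit4 fell by 0.43, while Cdkn1a stood at 167 CPM without and 156 with Dox (log2 -0.09, adjusted p = 0.775). Glycolysis genes were lower, 0 of 31 up and 2 down, Gpi1 (log2 -0.60) and Aldoc (log2 -0.43), with 1 and 8 over the list alone (adjusted p = 0.0385, and adjusted p = 0.749 with an estimated correlation). Fibroblast markers moved with these groups, 8 of 31 lower and 2 higher (13 and 2 over the list alone; adjusted p = 3.22e-08, and adjusted p = 0.749 with an estimated correlation), among them Acta2 (log2 -0.87), Col1a1 (log2 -0.69) and Bgn (log2 -0.61), with Ccn2 among those higher. The count fell to 6 without the 2nd sample without Dox (6 higher, 0 lower) and to 46 without the other, stood at 127 by DESeq2 and at 33 with all samples of the series in 1 fit. Of 29 named genes called, 26 lost the call without the 2nd sample without Dox, 19 without the other, and 11 and 9 without Dox samples 1 and 2.

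Retinoic acid for 4 d lowered the whole pluripotency list and raised retinoid-responsive, Hox and fibroblast marker genes in WT cells. Cyp26b1, which encodes an RA-degrading enzyme, rose from 42.1 ± 3.84 (n = 2) to 892 CPM in the single WT RA sample (log2 4.36, SE 0.16, edgeR adjusted p = 2.73e-17). Hoxa5 rose from 8.99 ± 1.67 to 262 CPM (log2 4.77). Nanog fell by 3.65, Esrrb by 3.31 and Sox2 by 2.97 on the log2 scale. The single sample was assumed to vary like the other groups of set 2. It was a single library, whereas both untreated WT samples summed libraries of both sub-batches, so its spread may be larger than assumed. Of 14659 tested genes, 6933 passed, 3631 higher and 3302 lower. The largest changes by the naming rule included rises in the Wnt antagonist gene Dkk2 (log2 6.41), the stathmin gene Stmn4 (log2 5.86), Nkain3 (log2 5.48), Wnt10b (log2 5.39) and Slitrk4 (log2 5.38) and falls in Foxd3 (log2 -5.55) and Tcf15 (log2 -5.11). Where a side held 1 to 3 counts, the ratio carried a wide interval, as for Uts2b (221-fold higher, 95% interval 38.2 to 8850), Zfp804a and Hoxb3 (70.7-fold higher, 18.4 to 603 for both) and Nr0b1 (96.1-fold lower, 26.5 to 796). The same held for falls in Slc7a7 (49.0-fold, 8.68 to 1947), Eras (36.7-fold, 12.5 to 179), Ak7 (33.1-fold, 5.82 to 1317) and Chrna9 (30.7-fold, 10.4 to 149), and for Cpne5 (interval 7.93 to 241). These intervals and the floors cover counting error only.

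In WT all 34 pluripotency genes fell with RA (34 over the list alone; adjusted p = 0.0468 with an estimated correlation), including Tdgf1 (log2 -3.72), Tdh (log2 -3.72) and L1td1 (log2 -3.63). Formative and primed genes had 17 of 25 lower and 4 higher, equally when adjusted over the list alone (adjusted p = 0.0427 with an estimated correlation), with Dnmt3b (log2 -2.90) and Etv5 (log2 -3.52) down and Sox4 (log2 2.76) up. Retinoic acid response and Hox genes had 28 of 37 higher and 1 lower (29 and 1 over the list alone; adjusted p = 0.0468 with an estimated correlation), including Tshz1 (log2 4.59). Markers of fibroblasts had 25 of 31 higher and none lower, equally over the list alone (adjusted p = 0.0291 with an estimated correlation). Acta2, the smooth muscle actin gene, went from 159 ± 22.4 to 4502 CPM, and Col1a1 from 31.7 ± 6.69 to 400. The other lists that passed with the preset correlation had higher p-values with an estimated one. Of 54 p53 targets 29 rose and 3 fell (29 and 3 over the list alone; adjusted p = 0.117 with an estimated correlation), with Cdkn1a at 72.6 CPM before and 575 after RA. Of 37 mitosis and DNA replication genes 34 fell (35 over the list alone; adjusted p = 0.117 with an estimated correlation), including Mcm5 (log2 -1.77). Of 44 ribosomal protein genes 33 fell (35 over the list alone; adjusted p = 0.0706 with an estimated correlation). Glycolysis genes had 19 of 31 lower and 4 higher (19 and 4 over the list alone), including Pdk1 (log2 -3.35), and imprinted genes 21 of 30 higher and 2 lower (21 and 3 over the list alone), including Grb10 (log2 2.34), each with adjusted p = 0.129 with an estimated correlation. Histone chaperones had 19 of 30 lower and 3 higher (22 and 4 over the list alone; adjusted p = 0.127 with an estimated correlation), with Nasp down by 1.52 and Set by 1.23. LIF-STAT3 genes had 5 of 19 higher and 6 lower, equally over the list alone, with a median log2 of 0.05 against a downward test (camera adjusted p = 0.0436, and adjusted p = 0.139 with an estimated correlation).

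In KO cells RA also raised retinoid-responsive and Hox genes and lowered pluripotency genes. Cyp26b1 rose from 45.7 ± 9.11 (n = 4) to 958 ± 77.4 CPM (n = 2; log2 4.27, SE 0.12, edgeR adjusted p = 1.19e-20). Hoxa5 rose by 4.42 and Nes, an intermediate filament gene of neural progenitors, by 2.23 on the log2 scale. Nanog fell by 3.06 and the Nodal inhibitor gene Lefty2 by 4.06. Of 14659 tested genes 8074 passed, 4145 higher and 3929 lower. By the naming rule the largest rises were in Duox2 (log2 6.52), Olr1 (log2 6.14), Slc16a12 (log2 5.54), Wnt10b (log2 5.42), Hoxb6 (log2 4.75), the keratin gene Krt20 (log2 4.67) and Prkg1, and Uts2b (125-fold, 95% interval 42.2 to 611 from 3 counts). The largest falls were in Trp73 (log2 -4.51), Foxd3 (log2 -4.39), Nr0b1 (log2 -4.33), Trh (log2 -4.30), Epp13 (log2 -4.21), Zscan5b (log2 -4.19), Rbp7 (log2 -4.17) and Chrna9 (46.2-fold, 15.6 to 225). Of 34 pluripotency genes 33 fell (33 over the list alone; adjusted p = 0.0440 with an estimated correlation), and of 25 formative genes 21 fell and 4 rose, equally over the list alone (adjusted p = 0.0126 with an estimated correlation). Of 37 retinoic acid response and Hox genes 33 rose and 2 fell, equally over the list alone (adjusted p = 0.00341 with an estimated correlation). Of 31 fibroblast markers 27 rose and 2 fell, equally over the list alone (adjusted p = 0.0440 with an estimated correlation). Endoderm genes had 18 of 26 higher and 4 lower (19 and 6 over the list alone; camera adjusted p = 0.000298), with adjusted p = 0.0640 with an estimated correlation. In WT 11 of 26 were higher and 4 lower (11 and 5 over the list alone; camera adjusted p = 0.0217), with adjusted p = 0.181 with an estimated correlation. Pou5f1, with a log2 change of -2.07 (adjusted p = 0.00442), lost its call without KO1 sample 2d (adjusted p = 0.268) and without KO RA sample 2i (adjusted p = 0.0628). Ctnnb1 (log2 0.44, adjusted p = 0.0355) lost its call without samples 2d (adjusted p = 0.0782), 2e (adjusted p = 0.0615) and 2i (adjusted p = 0.692). It also lost it against KO1 controls alone (adjusted p = 0.146), the line in the titles of both KO RA samples, by DESeq2 (adjusted p = 0.118) and with every library as its own sample (adjusted p = 0.0530).

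After RA, endoderm genes were higher in the 2 KO samples than in the single WT sample. That sample was assumed to vary like the other groups of set 2, so a deviation of its own is not told apart from an effect of genotype. It was a single library, whereas both untreated WT samples summed libraries of both sub-batches, so its spread may be larger than assumed. Lama1, the laminin α1 gene (chromosome 17, 67697259 to 67822647), was higher in both KO samples than in the WT sample, at 104 ± 15.0 CPM (n = 2) in KO (log2 1.85, SE 0.23, edgeR adjusted p = 8.24e-05). Cited1 stood at 14.9 and 54.5 ± 4.78 (log2 1.82, SE 0.26, adjusted p = 0.000436) and H19 at 28.3 and 124 ± 18.3 (log2 2.09, SE 0.24, adjusted p = 5.67e-05). Sox17 (log2 1.70), Col4a1 (log2 0.99), the endoderm factor gene Gata4 (log2 2.55) and Hs3st1 (log2 1.78) were also higher in KO. Tfap2b, a neural crest factor gene, stood at 31.8 CPM in WT and 4.72 ± 2.32 in KO (log2 -2.78, SE 0.43, adjusted p = 0.00130), and Nr2f1, an RA-induced nuclear receptor gene, at 193 and 94.1 ± 7.52 (log2 -1.08). Of 14659 tested genes 58 passed, 42 higher and 16 lower, with Hkdc1 (log2 2.35) and Srgn (log2 2.27) among the highest and Tcim (log2 -1.54), Crmp1 (log2 -1.17), Mgmt (log2 -1.16) and Slc1a3 (log2 -1.05) among the lowest. Of 26 endoderm genes 11 were higher and none lower (19 when adjusted over the list alone; camera adjusted p = 3.69e-42, and 0.00752 with an estimated correlation), and the 11 included no fibroblast marker. Fibroblast markers had 0 of 31 called, 0 over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.607 with an estimated correlation; median log2 0.06), with 929 genes at an unadjusted p under 0.05 and 43 genes called by DESeq2. The count was 34 without KO RA sample 2h, 15 without KO RA sample 2i, 94 without KO2 sample 2e and 98 without KO2 sample 2f. It was 94 without a low-count filter and 8 with every library as its own sample. Of 22 named genes called, 15 lost the call without sample 2i, Gata4 (adjusted p = 0.0621) and Tfap2b (adjusted p = 0.0829) among them, 11 without sample 2h and 5 by DESeq2. With every library as its own sample 19 of the 22 lost it, among them Sox17, Hs3st1, Col4a1 (adjusted p = 0.289), Nr2f1 (adjusted p = 0.237), Gata4 (adjusted p = 0.0562) and Tfap2b (adjusted p = 0.143). H19, Lama1 and Cited1 kept theirs in every fit.

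Other lists passed after RA only with the preset correlation. Pluripotency genes (0 of 34 called, 3 higher over the list alone; adjusted p = 0.0225) and retinoic acid response and Hox genes, where Cyp26a1 was higher (log2 0.91) and Tshz1 lower (log2 -0.77) among 37 (1 and 3 over the list alone; adjusted p = 0.0246), each had adjusted p = 0.607 with an estimated correlation. So did glycolysis genes (1 of 31 higher, P4ha2, log2 1.00, and 1 over the list alone; adjusted p = 0.0247). Trophectoderm genes (1 of 17 higher, Krt8, log2 0.87, and 3 over the list alone; adjusted p = 0.0181) had adjusted p = 0.573 with an estimated correlation. Germline genes (1 of 24 higher, Taf7l, log2 1.48; 2 higher and 1 lower over the list alone; adjusted p = 0.0181) had adjusted p = 0.379 with an estimated correlation. Krt8, Cyp26a1, Tshz1, P4ha2 and Taf7l all lost their calls without sample 2i (adjusted p = 0.444, 0.278, 0.215, 0.192 and 0.314) and without sample 2h (adjusted p = 0.160, 0.0783, 0.239, 0.127 and 0.136). All 5 also lost them with every library as its own sample. Krt8 did so by DESeq2 (adjusted p = 0.0884) and without WT 2a (0.0567), WT 2b (0.0662), KO1 2c (0.0648) and KO1 2d (0.0716), Taf7l by DESeq2 (adjusted p = 0.153) and Tshz1 with all samples in 1 fit (adjusted p = 0.0691).

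**Figure D4:**
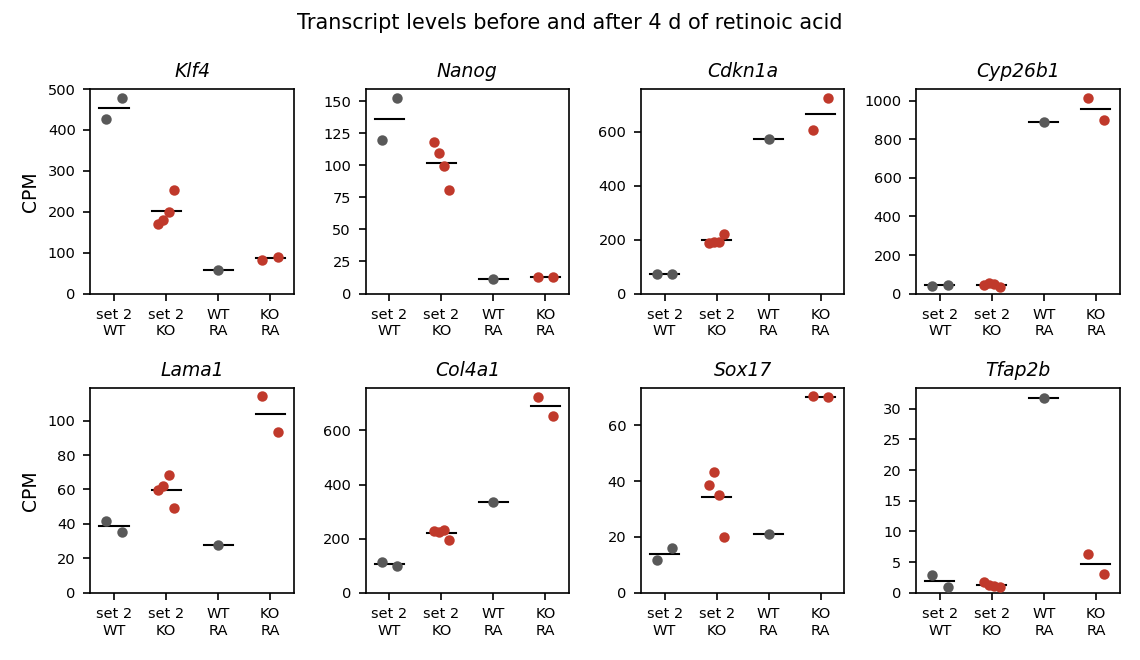
Transcript level in CPM (y axes) of 8 genes in set 2 samples (points) by group (x axes), with the group mean as a line; grey is WT and red is KO, and the WT RA group is 1 sample. Klf4 and Nanog were lower and Cyp26b1 higher after RA in both genotypes, while Lama1 and Sox17 were higher in the 2 KO RA samples than in the WT RA sample.

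In the test of the RA effect in KO against that in WT, 160 of 14659 genes passed, 51 with a higher and 109 with a lower value in KO, and 2 with every library as its own sample. The WT RA arm was 1 sample, assumed to vary like the other groups, and a deviation of that sample would enter the difference of every gene. The RA samples were single libraries, whereas WT samples 2a and 2b each summed libraries of both sub-batches, which averages the difference between sub-batches. The assumed spread may therefore be too small for an RA library, whose sub-batch was not determined. For Klf4 the SE of the difference was 0.21, and 0.52 with every library as its own sample. Klf4 fell by 3.01 on the log2 scale in WT and by 1.32 in KO (difference 1.69, edgeR adjusted p = 5.30e-05), from 453 to 57.9 CPM and from 201 to 85.9. Cdkn1a rose by 2.95 in WT and by 1.65 in KO (difference -1.30, adjusted p = 0.000276), from 72.6 to 575 CPM and from 198 to 668. Lrrn4 rose by 1.27 in WT and fell by 1.30 in KO (adjusted p = 0.000276). Pluripotency genes fell less in KO (4 of 34 called, 19 over the list alone; camera adjusted p = 3.27e-19) and p53 targets rose less (5 of 54 called, 13 over the list alone; camera adjusted p = 6.11e-08), both with adjusted p = 0.151 with an estimated correlation. Fibroblast markers also rose less in KO (1 of 31 called, 8 over the list alone; camera adjusted p = 2.17e-06), with adjusted p = 0.158 with an estimated correlation. Of 12 lists that passed with the preset correlation, 0 did so with an estimated one. The RA by genotype difference is the KO minus WT difference after RA minus that before RA, so it also holds the KO effect before RA. Before RA in set 2, 19 of 34 pluripotency genes were lower in KO and 1 higher. Of 54 p53 targets, 19 were higher in KO and 0 lower. A smaller fall or rise in KO therefore does not by itself show a weaker response to RA. By the naming rule the highest differences were in Sall3 (2.44), Rapgef3 (2.22) and Sgms2 (2.06) and the lowest in Vgf (-2.84), Lzts1 (-2.84) and Lrrn4 (-2.57). The count was 27 without WT sample 2b, 95 without WT 2a, 388 without KO2 2f, 27 without KO RA sample 2h and 59 without 2i, 98 by DESeq2 and 284 without a low-count filter. With every library as its own sample Klf4 (adjusted p = 0.601) and Cdkn1a (adjusted p = 0.101) lost their calls, which they kept in every other fit. Lrrn4 kept its call in every fit, while Sall3 (adjusted p = 0.111), Rapgef3 (adjusted p = 0.105), Sgms2 (adjusted p = 0.202), Vgf (adjusted p = 0.133) and Lzts1 (adjusted p = 0.151) lost theirs without WT sample 2b. In the same order these 5 lost them without KO RA sample 2i (adjusted p = 0.0772, 0.0585, 0.104, 0.0783 and 0.114) and with every library as its own sample (adjusted p = 0.910, 0.498, 0.499, 0.222 and 0.354). Sall3, Sgms2, Vgf and Lzts1 lost them without 2h (adjusted p = 0.0716, 0.143, 0.0731 and 0.107), and Sgms2, Vgf and Lzts1 without WT 2a (adjusted p = 0.0644, 0.0504 and 0.0534). Lzts1 also did so without KO2 2e (adjusted p = 0.0525) and Sgms2 by DESeq2 (adjusted p = 0.166).

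The KO effect in set 1 was compared with the RA effect in WT of set 2, which share no samples. Krt19 and Cdkn1a were higher and Klf4 and Esrrb lower in both. Across 9704 genes the log2 changes correlated with r = 0.486 and rho = 0.424, where genes are not independent replicates. Of genes called in both, 496 were higher in both (177 if the lists were independent), 344 lower in both (146) and 78 in opposite directions, which is 8.50% of 918. The KO effect over both sets and the Dox effect hardly correlated across 11037 genes (r = -0.0452, rho = -0.0314). Of 53 genes called in both, 54.7% went in opposite directions. There were 14 higher in both (10.6 if the lists were independent), 10 lower in both (7.80) and 16 and 13 in opposite directions (8.44 and 9.75). Mdm2 and Ccn2 rose in both, while Tfcp2l1 and Zfp42 fell in KO and rose with Dox, and H19 rose in KO and fell with Dox.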

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

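Of 150 groups of 4 samples examined, 11 had a sample far from the other 3 by Dixon's ratio of gap to range, which is 7.33%, where chance gives about 1 in 20. In set 2 KO, sample 2f stood apart for Cdkn1a (221 against 188 to 193 CPM, ratio 0.847), Foxa2 (56.2 against 65.3 to 65.8, 0.955), Col4a1 (194 against 225 to 230, 0.863), Id2 (133 against 179 to 188, 0.845) and Cd81 (106 against 145 to 151, 0.857). Sample 2c did so for Inhbb (1.46 against 3.64 to 3.94, 0.878) and Pola1 (106 against 121 to 123, 0.871). In set 1 KO, sample 1e did so for Vgf (24.8 against 11.8 to 12.5, 0.947). Sample 1d did so for Tfap2c (156 against 134 to 137, 0.864), Pola1 (98.8 against 89.7 to 91.1, 0.844) and Isg15 (2.58 against 6.87 to 7.51, 0.871). All flags in set 2 fell on 2f, a library of sub-batch A, or 2c, a library of sub-batch B. Samples 2d and 2e summed libraries of both sub-batches. Whether sub-batch set 2c and 2f apart was not tested.

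The KO effect differed between the sets by the edgeR interaction test for several named genes, given as the log2 effect in set 2 minus that in set 1. It was higher in set 2 for Set (3.94), Stra8 (2.35), Triml1 (1.43) and Lef1 (1.13). It was lower in set 2 for Acta1 (-4.47), Sema3c (-4.41), Ccn4 (-4.39), H19 (-3.75), Krt8 (-2.42), Nes (-2.17), Peg3 (-1.47), Ifitm3 (-1.06), Sparc (-0.99) and Peg10 (-0.93). Each of these kept the sign of its effect in both sets.

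The RA effect differed between genotypes by the edgeR test, given as the log2 effect in KO minus that in WT. This difference also holds any KO effect present before RA. It was higher in KO for Sall3 (2.44), Rapgef3 (2.22), Sgms2 (2.06), Etv4 (1.70), Klf4 (1.69) and Slc7a5 (0.88). It was lower in KO for Vgf (-2.84), Lzts1 (-2.84), Lrrn4 (-2.57), Lefty2 (-1.65), Stmn4 (-1.38), Krt19 (-1.35), Cdkn1a (-1.30), Id2 (-1.12), Jun (-1.06), Tshz1 (-1.03), Grb10 (-0.84), Plk2 (-0.83) and Phlda3 (-0.81). Rapgef3, Sgms2, Lzts1 and Lrrn4 had effects in opposite directions in the genotypes.

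Technical and biological explanations were weighed for the difference of the KO effect between sets, 1 of them chosen only after the result was seen. Gain or loss of a chromosome in a line would place these genes on shifted chromosomes, and 0% of the 99 genes lay on one. The Y chromosome did shift, by a median log2 of -6.85, but none of its 4 tested genes was called. Of 3 tested genes of the Y-linked list 2 had a lower KO effect in set 2 when adjusted over the list alone (median log2 -8.12), so the change of Y is left open. More feeder RNA in set 1 KO would lower the set difference of feeder markers, and the median over 27 markers was -1.29, as this predicts. That median is part of the set difference itself, reported above, so it is no separate evidence for feeder content. Col1a1, Col1a2 and Col3a1 together also went from 55.6 CPM in set 2 WT to 632 in the WT RA sample. Such markers may therefore not track feeder content alone. Scaling the KH2 profile to the collagen level, the test chosen afterwards, gave a median of only 3.94% of the set 1 rise over 79 genes, so KH2-like fibroblast content leaves most of it open. The sets also differ in remaining Set transcript, a biological explanation that was not tested.

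The RA library of KO sample 2i is titled KO1 but held 4.42 CPM of Ddx3y, near the KO2 level of set 2 (6.77). Sample 2h held 51.0 CPM, between the levels of untreated KO1 (30.9) and untreated WT (65.7) of set 2. A mislabelled sample could give the level in 2i, and 0 called genes off the Y chromosome could be compared. Of 133 genes off the Y chromosome with an unadjusted edgeR p under 0.01 between the lines, 63.2% went in the KO2 direction. KO1 sample 2c was a sub-batch B library and KO2 sample 2f a sub-batch A library, so these genes may follow sub-batch instead of line. The label and a swap therefore cannot be told apart. Y-linked levels also changed between lines and sets without any RA, so loss of Y-linked expression in culture is a biological alternative.

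Hbb-bs reads appeared with Dox only. RNA of erythroid cells would raise other erythroid genes with it, and 19 of them rose by 2.48% of the rise of Hbb-bs, which speaks against that source. Globin sequence in the induced construct could also give such reads and was not tested.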

How the results depend on the processing

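No call of a named gene was reversed by an alternative. The balance of calls did move, from 0 higher and 3 lower to 31 and 25 for KO2 against KO1 in set 2 without 2e, and from 114 and 115 to 148 and 86 for Dox without Dox sample 2. Gene list tests and correlations were run under 1 alternative each. DESeq2 size factors moved no count by more than 1.5 times. The sub-batch alternatives and the endoderm list without feeder members were chosen after the data were seen. Sub-batches were cut from the same libraries, so fits with or within them tend to have a smaller remaining spread by construction. The cause of the shifts below was not tested. Summing libraries per line and set gave 1426 genes for KO against WT in place of 2194. Treating every library as its own sample gave 759 for KO in set 2, 1 for KO2 against KO1 in set 2, 8 for KO after RA and 2 for the RA by genotype difference. Without a low-count filter the set by genotype difference had 171 genes, KO2 against KO1 25 in set 1 and 22 in set 2, KO after RA 94 and the RA by genotype difference 284. DESeq2 gave 127 for Dox and 98 for the RA by genotype difference, and 1 fit of all samples gave 33 for Dox. Sub-batch A alone gave 434 for KO in set 2, and sub-batch as a covariate, with every library as its own sample, 184 for the set by genotype difference, where every library alone gave 78. With an estimated correlation the lists called fell from 14 to 9 for KO over both sets, 15 to 5 in set 1, 14 to 2 in set 2, 4 to 1 for the set by genotype difference, 1 to 0 and 2 to 0 between lines in sets 1 and 2, 4 to 0 for Dox, 16 to 4 and 15 to 4 for RA in WT and KO, 7 to 1 for KO after RA and 12 to 0 for the RA by genotype difference. The correlation of set 1 KO with RA went from 0.486 to 0.529 on genes of at least 10 CPM. Leaving out 1 sample, with a lone remaining sample assumed to vary like the other groups, gave 1553 to 2416 genes for KO over both sets, 570 to 1388 in set 1, 195 to 2335 in set 2, 22 to 127 for the set by genotype difference, 1 to 196 and 1 to 56 between lines in sets 1 and 2, 6 to 234 for Dox, 5558 to 7224 and 6191 to 7919 for RA in WT and KO, 15 to 98 for KO after RA and 27 to 388 for the RA by genotype difference. Of the named genes called, 61 of 70 kept the call everywhere for KO, 1 of 29 for Dox, 90 of 92 and 88 of 90 for RA in WT and KO and 3 of 22 for KO after RA. With the replicate number as a replicate block the counts were 1032 for KO in set 1, 1 for KO2 against KO1 in set 1 and 724 for Dox. With the block and every library as its own sample they were 1738 for KO over both sets, 454 in set 2, 43 for the set by genotype difference and 1 for KO2 against KO1 in set 2, beside 2014, 759, 78 and 1 without the block. T had adjusted p = 0.174 with the block and 0.0478 without it, and for the set by genotype difference Acta1 (0.0885) and Triml1 (0.0597) lost their calls with it. Deviations from the group mean of libraries sharing a number correlated between -0.0583 and 0.0188 in set 1, between -0.217 and 0.172 in set 2 and at 0.0271 in KH2 cells. With 2 libraries per group, as in set 1 and KH2 cells, libraries with different numbers give the same values with the sign reversed. Such correlations over all genes do not rule out pairing, and the block raised the Dox count from 229 to 724. Whether the numbers pair the samples is left open. In simulated data 56% of 2-fold changes were recovered in set 1 and 72% in set 2.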

Other observations

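Genes in this paragraph were chosen after their values were seen. Within the lists that did not pass for KO against WT, neuronal genes split. The neurofilament gene Nefl (log2 1.36) and the growth cone gene Gap43 (log2 1.65) rose, whereas Stmn2 (log2 -0.99) and the RNA-binding protein gene Elavl3 (log2 -1.03) fell. The acidic nuclear protein gene Anp32a (log2 -0.59), whose product binds SET-related complexes, and the H3.3 chaperone gene Hira (log2 -0.76) fell, as did the PP2A regulatory subunit gene Ppp2r5a (log2 -1.24). The retinoic acid receptor genes Rarg (log2 -0.97) and Rara (log2 -0.56) fell. Pfkp, a glycolysis enzyme gene, fell by 1.43, and Dppa3 was the pluripotency gene that rose (log2 1.02).

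Libraries of set 2 that share a title code were less alike than libraries within a sub-batch. Their deviation over sampling noise (chi-square per degree of freedom) was 4.46 for 2a, 8.73 for 2b, 5.79 for 2d and 7.78 for 2e, while pairs of a group within a sub-batch ran from 1.77 to 2.98. The sub-batches were cut from the profiles of these same libraries, so pairs within them were bound to be more alike. Genes such as Bgn and Mmp3 were higher in sub-batch A and Rasd1 and Socs3 in sub-batch B.

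The count of 2194 genes between KO and WT was set against splits of the same 12 samples within their sets. Only 1 of 100 splits, the real one, had as many calls, and the highest other split had 235. Every other split mixed WT and KO samples on a side, so the KO effect entered the spread between samples and lowered the calls. The splits therefore do not give the count to be found without a KO effect.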
